A study of Homo sapiens with 9 samples.

How the data were processed

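RNA sequencing was carried out on HTR-8/SVneo, an established line of human placental trophoblast cells. The 9 libraries formed 3 groups of 3, which were control cells kept in 21% oxygen, cells kept in 1% oxygen and cells given sodium L-lactate at 25 mM. The labels give a treatment time of 24 h for hypoxia and lactate, and give neither a time for the control nor an oxygen level for the lactate group. They do not say whether the 3 replicates of a group were separate cultures, so the replicates may be technical. RNA was taken up in Trizol, and a standard Illumina protocol was used to build the libraries.

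The authors deposited 1 table of raw read counts per Ensembl gene, with a column for each library and no normalization. A deposited gene length in bases, a quantity other than expression, stands beside the counts and was not used. The deposited notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the GRCh38 genome build, with no role for either tool. The selection of RNA, the strand setting, the annotation release and the handling of reads that map to several genes are not stated. Values of genes with close paralogs or pseudogenes, and of genes that overlap another on the opposite strand, therefore carry an uncertainty that the table cannot resolve. The table holds 58735 genes. All 58735 identifiers were found in GENCODE release 29 (Ensembl 94), and 58724 had the same start and end there, so coordinates below are on GRCh38.

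Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its defaults, which left 15822 genes, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation and a mean for each group was fitted to all 9 libraries. The 3 contrasts were hypoxia against normoxia, lactate against normoxia and hypoxia against lactate. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested within each contrast, with a threshold of 0.05. Genes past this threshold with an absolute log2 fold change of at least 1 were counted as well. Fitted fold changes used a prior count of 0.125. Levels (CPM) are read counts normalised to a common TMM-scaled library total, given as mean ± SD of 3 libraries, and errors of log2 fold changes are standard errors (SE) from the fit.

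Library totals ranged from 15462298 to 17419681 counts. A floor of 3 counts corresponds to between 0.172 and 0.194 CPM, and values near it are limited by counting. Reads carry no molecular identifiers in the table, so such floors cover counting error only. The common biological coefficient of variation of the fit was 0.0727. The tests were also run on simulated data built from these libraries, with 50 changed genes at each of several folds. In the hypoxia design edgeR recovered 18% of genes changed 1.25-fold, 56% at 1.5-fold, 82% at 2-fold and 88% at 4-fold, with 7 false calls. In the lactate design it recovered 30%, 68%, 78% and 96%, with 8 false calls. DESeq2 recovered 18%, 54%, 76% and 84%, then 28%, 68%, 74% and 94%, with 8 and 6 false calls.

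Before the data were examined, the contrasts, tests, alternatives, 39 gene lists and the rule for named genes were fixed. The lists cover glycolysis, hypoxia-inducible factor (HIF) targets and pathway members, lactate handling, matrix, proteases, respiration, the cell cycle, lipids, stress responses, immunity, growth factors, epithelial and mesenchymal genes, placental and other cell type markers, chromatin, ribosomes, pH and autophagy. Of the list members, 3 matched no gene in the table, and 52 were matched through a current symbol. Symbols are printed as the table gives them. The 37 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation and fry were run beside it. On simulated data each of these 3 tests called the changed list and 0 of 38 unchanged lists. Genes were drawn there independently and unchanged lists at random, so this does not show how the tests treat lists of correlated genes.

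Named genes were chosen by the following rule. For each contrast against normoxia they are the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold. These needed a mean of at least 5 CPM and all 3 treated libraries on the same side of all 3 normoxia libraries. For hypoxia against lactate the 5 largest each way were taken. For genes changed in both treatments, also protein-coding and of at least 5 CPM, the rule takes the 10 with the largest smaller change in the same direction and the 5 in opposite directions. HIF1A, EPAS1, VEGFA, CA9, SLC2A1, LDHA, LDHB, SLC16A1, SLC16A3, PDK1, FN1, SERPINE1, FLT1, PGF, ENG, EP300 and HLA-G were always included. In each list the 2 members with the smallest p in each direction were included. Any other gene is named because it belongs to a count of 5 or fewer or was singled out, after its values were seen.

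The overlap of the 2 treatments was set beside the overlap of independent lists and beside 30 simulations. Each simulation compared 2 unchanged groups with the same normoxia libraries, since a shared control alone gives correlated fold changes. The 3 controls cannot be split into independent sets with replicates. The alternatives were another scaling (RLE), the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter of 1 CPM in at least 3 libraries, the replicate number as a block and estimation without robustness. Mitochondrially encoded genes were left out, a fold threshold was added, fits used only the 6 libraries compared, and each library was left out in turn. No pair of libraries was found to be a duplicate, and no library was left out of the reported values. FLT1 and HLA-G did not pass the filter on low counts.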

Results

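Gene expression was measured by RNA sequencing in HTR-8/SVneo, a line of human trophoblast cells derived from placental tissue. The 3 groups were control cells in normoxia at 21% oxygen, cells in hypoxia at 1% oxygen for 24 h and cells given 25 mM sodium L-lactate for 24 h, with 3 libraries in each. Total counts were 17287119, 17281924 and 16776100 in normoxia replicates 1, 2 and 3. They were 16918384, 16727795 and 15462298 in hypoxia, and 17419681, 16939219 and 17154761 in lactate, so that every hypoxia total was below every lactate total. Mitochondrially encoded genes took 3.15%, 3.14% and 3.16% of counts in normoxia, 2.59%, 2.67% and 2.67% in hypoxia and 3.23%, 3.09% and 3.36% in lactate. The 10 most abundant genes of a library took between 5.95% and 6.78% of its counts.

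Hypoxia was the main difference among the libraries. On the plot of principal components it stood apart along the axis that carried 63.0% of the variance, while normoxia and lactate stood apart along the next, with 7.76%. Log CPM of libraries of 1 group correlated across genes at Pearson r between 0.989 and 0.992. The labels and files give no batch or date. Levels below are mean ± SD of n = 3 libraries in counts scaled for depth (CPM). A floor of 3 counts lay between 0.172 and 0.194 CPM. Values of AKR1C1 to AKR1C3, the BTN3A, CGB and PSG genes, class I HLA genes, histones, HSPA1A and HSPA1B and metallothioneins may hold reads from close relatives of each gene. FLT1, with 0 to 5 counts per library, and HLA-G, with 0 to 1, did not pass the filter on low counts.

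**Figure D1:**
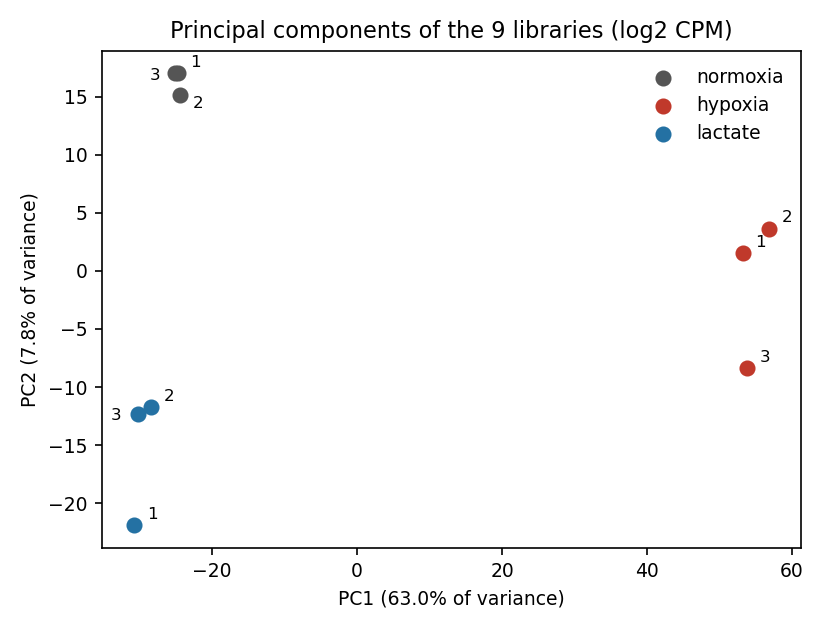
Principal components of log2 CPM for the 9 libraries, the horizontal axis holding 63.0% and the vertical axis 7.76% of the variance; each point is a library, coloured by group and numbered by replicate. The 3 hypoxia libraries lie apart from the other 6, and the lactate libraries lie below the normoxia libraries.

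Hypoxia was compared with normoxia to show what low oxygen changes in these cells. As lists, low oxygen raised HIF targets and genes of sugar breakdown, vessel growth and matrix, and lowered NRF2 targets and interferon-stimulated genes. Cytosolic heat shock and mitochondrially encoded respiratory genes were lower too, but these calls did not hold with an estimated correlation (adjusted p = 0.103 and 0.124). ANGPTL4, a secreted inhibitor of lipoprotein lipase and a HIF target, rose from 3.21 ± 0.496 CPM to 266 ± 9.6 CPM. VEGFA, the main growth factor for vessels, rose from 20.8 ± 0.683 CPM to 153 ± 20.7 CPM, and LDHA, which turns pyruvate into lactate, from 827 ± 9.13 CPM to 3048 ± 64 CPM. NQO1, a quinone reductase under the antioxidant regulator NRF2, fell from 346 ± 7.88 CPM to 103 ± 3.02 CPM. IFIH1, a sensor of viral RNA, fell from 12.8 ± 1.08 CPM to 2.47 ± 0.213 CPM.

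In all, 7695 of 15822 genes tested (48.6%) passed an adjusted p below 0.05, 3697 of them higher and 3998 lower in hypoxia. Of these, 1600 changed at least 2-fold, 767 up and 833 down. For 9359 genes (59.2%) the 3 libraries of each group did not overlap, where chance gives 10% with 3 libraries against 3. Processed pseudogenes rose more often than they fell, 95 against 27 of 517 tested, as did antisense transcripts, 162 against 106 of 924. Long intergenic RNAs showed 119 up and 93 down of 606.

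The largest rises among protein-coding genes past the naming rule were those of FAM83A (6.40), ANGPTL4 (6.37), INHBB (5.88), CA9 (5.74) and TGFBI (4.46), given as log2 fold changes. FAM83A is a partner of growth factor signalling, INHBB a subunit of activins and inhibins, and TGFBI a matrix protein induced by TGF-beta. STC2, NDRG1, PPFIA4, ERRFI1 and TCAF2 followed, with log2 fold changes of 4.16, 4.12, 3.87, 3.76 and 3.70. The largest falls were those of IGFN1 (-4.74), PIR (-3.75), ZNF467 (-3.63), PALM3 (-3.46) and BTN3A2 (-3.38). PIR, an iron-binding cofactor, is itself an NRF2 target, and BTN3A2 and BTN3A3 (-3.14) are butyrophilins that activate gamma-delta T cells. ARG2, PCDH18, P2RX6 and COL3A1 fell with log2 fold changes of -3.34, -3.30, -3.27 and -3.11.

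Among HIF target genes outside glycolysis, 36 of the 41 measured rose, 1 fell and 4 did not pass the test (median 1.41, camera adjusted p = 1.28e-86). Unless given, counts adjusted over the list alone were the same as those over all genes in this comparison. ANGPTL4 (log2 fold change 6.37, SE 0.12, adjusted p = 3.88e-22) and NDRG1 (log2 fold change 4.12, SE 0.09, adjusted p = 4.21e-21) had the smallest p, and PLOD1 (log2 fold change -0.27, SE 0.08, adjusted p = 0.00521), a lysyl hydroxylase for collagen, was the member that fell. NDUFA4L2, which damps complex I, had -0.34 (adjusted p = 0.576). CA9, a carbonic anhydrase at the cell surface, rose from 0.53 ± 0.328 CPM to 28.8 ± 3.12 CPM. For glycolysis and glucose uptake, 24 of the 25 measured rose, 1 fell and 0 did not pass the test (median 1.03, camera adjusted p = 4.15e-52). LDHA (1.88), PGK1 (1.92), PDK1 (2.83) and the glucose carrier SLC2A1 (2.16) rose, and PFKM, the muscle phosphofructokinase, fell (-0.73).

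The positions of the main genes on GRCh38 are as follows. ANGPTL4 is ENSG00000167772, chromosome 19, 8363289 to 8374373. VEGFA is ENSG00000112715, chromosome 6, 43770184 to 43786487. LDHA is ENSG00000134333, chromosome 11, 18394388 to 18408425. HIF1A is ENSG00000100644, chromosome 14, 61695513 to 61748259. FN1 is ENSG00000115414, chromosome 2, 215360440 to 215436172. SERPINE1 is ENSG00000106366, chromosome 7, 101127089 to 101139266. NQO1 is ENSG00000181019, chromosome 16, 69706996 to 69726951. AKR1C1 is ENSG00000187134, chromosome 10, 4963253 to 4983283. IFIH1 is ENSG00000115267, chromosome 2, 162267079 to 162318703. CA9 is ENSG00000107159, chromosome 9, 35673856 to 35681159. DUSP1 is ENSG00000120129, chromosome 5, 172768090 to 172771195. ACTC1 is ENSG00000159251, chromosome 15, 34788095 to 34795726.

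The oxygen-regulated transcription factors themselves moved differently. HIF1A transcripts fell from 464 ± 17.5 CPM to 269 ± 40.8 CPM (log2 fold change -0.78, SE 0.09, adjusted p = 1.04e-07), and EPAS1, which encodes HIF-2 alpha, had 0.09 (adjusted p = 0.369). Of the HIF pathway components, 2 of the 9 measured rose, 2 fell (1 without normoxia replicate 2 or 3 or hypoxia replicate 3) and 5 did not pass the test (median 0.09, camera adjusted p = 0.371). CITED2, a competitor for EP300, rose (1.31), as did the prolyl hydroxylase EGLN1 (0.28), and ARNT fell (-0.20; adjusted p up to 0.0936 without normoxia replicate 2 or 3 or hypoxia replicate 3). EP300 had -0.19 (adjusted p = 0.144). In lactate and pyruvate handling, 6 of the 23 measured rose, 5 fell and 12 did not pass the test (median 0.03, camera adjusted p = 0.0675). The lactate exporter SLC16A3 rose (0.81), while PC (-0.87), which carboxylates pyruvate, and SLC16A7 (-0.67) fell. LDHB had 0.03 (adjusted p = 0.826) and SLC16A1 -0.04 (adjusted p = 0.683).

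Matrix and vessel genes rose more often than they fell. For extracellular matrix and fibrosis, 23 of the 37 measured rose, 9 fell and 5 did not pass the test (median 0.42, camera adjusted p = 2.97e-09). LOX, which crosslinks collagen, rose by log2 3.68 and TGFBI by 4.46, whereas COL3A1 fell (-3.11), as did LAMB1 (-1.09). Fibronectin, encoded by FN1, rose from 1135 ± 40.7 CPM to 4325 ± 401 CPM, and SERPINE1, the inhibitor of plasminogen activators, from 100.1 ± 2.98 CPM to 477 ± 56.9 CPM. In the metalloproteinase and plasminogen list, 6 of the 15 measured rose, 6 fell and 3 did not pass the test (median 0.06, camera adjusted p = 0.0733). PLAUR (1.48) rose and SERPINE2 (-0.67) and MMP15 (-0.84) fell. Of angiogenic factors and receptors, 12 of the 21 measured rose, 2 fell and 7 did not pass the test (median 0.44, camera adjusted p = 1.37e-10). PGF rose (2.11), NRP1 (-1.89) and EFNA1 (-1.69) fell, and ENG had 0.44 (adjusted p = 3.47e-05). Of mesenchymal transition regulators, 11 of the 17 measured rose, 2 fell (1 without normoxia replicate 3 or hypoxia replicate 1, 4 without hypoxia replicate 3) and 4 did not pass the test, or 11 up and 3 down adjusted over the list alone (median 0.22, camera adjusted p = 0.00146, but adjusted p = 0.0709 with an estimated correlation). SMAD7 (2.38) and FOXC2 (1.65) rose and TWIST1 (-0.95) fell.

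Of immediate early genes, the fast transcriptional targets of growth factor and stress kinases, 15 of the 25 measured rose, 6 fell and 4 did not pass the test (median 0.83, camera adjusted p = 3.17e-11, but adjusted p = 0.0635 with an estimated correlation). JUN (2.21) and the phosphatase DUSP1 (2.28) rose, and JUND (-0.53) and EGR1 (-0.69) fell. Among ATF4 targets of the amino acid response, 20 of the 38 measured rose, 11 fell and 7 did not pass the test (median 0.31, camera adjusted p = 0.000111, but adjusted p = 0.162 with an estimated correlation). STC2 (4.16) and the amino acid carrier SLC7A5 (1.69) rose, and PSPH (-1.37), of serine synthesis, and GDF15 (-1.35) fell.

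No NRF2 target rose among the 24 measured, 19 fell and 5 did not pass the test (median -0.78, camera adjusted p = 8.23e-16). NQO1 (log2 fold change -1.75, SE 0.06, adjusted p = 1.2e-16) and the transketolase gene TKT (-1.10) had the smallest p, and SRXN1 had 0.06 (adjusted p = 0.83). Of interferon-stimulated genes, 0 of the 33 measured rose, 27 fell and 6 did not pass the test, or 0 up and 28 down adjusted over the list alone (median -0.93, camera adjusted p = 2.02e-12). IFIH1 (log2 fold change -2.38, SE 0.15, adjusted p = 3.54e-12) and PARP14 (-1.49) led it. In class I antigen presentation, 5 of the 15 measured rose, 8 fell and 2 did not pass the test, or 5 up and 9 down adjusted over the list alone (median -0.30, camera adjusted p = 0.161). HLA-E (0.93) and HLA-A (0.55) rose, while the immunoproteasome subunit PSMB9 (-2.97) and the peptide trimmer ERAP2 (-1.58) fell. For NF-kB and inflammatory cytokines, 8 of the 17 measured rose, 5 fell and 4 did not pass the test, or 8 up and 6 down adjusted over the list alone (median 0.22, camera adjusted p = 0.118). LIF (2.17) and IER3 (1.15) rose and NFKB2 (-0.62) and NFKBIA (-0.53) fell.

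Protein folding genes of the cytosol fell as well. In the heat shock list, 1 of the 21 measured rose (0 without normoxia replicate 3 or hypoxia replicate 2 or 3), 18 fell and 2 did not pass the test (median -0.39, camera adjusted p = 7.47e-07, but adjusted p = 0.103 with an estimated correlation), with HSPA1B (-1.01) and HSPH1 (-0.88) having the smallest p. The unfolded protein response of the endoplasmic reticulum showed a mixed picture, as 9 of the 25 measured rose, 4 fell and 12 did not pass the test, or 9 up and 5 down adjusted over the list alone (median 0.12, camera adjusted p = 0.307). HERPUD1 (0.59) and HSPA5 (0.39) rose and PDIA4 (-0.48) and SEC24D (-0.47) fell. Among osmotic stress targets of NFAT5, 4 of the 13 measured rose, 5 fell and 4 did not pass the test, or 5 up and 6 down adjusted over the list alone (median -0.21, mean 0.57, test upward; camera adjusted p = 0.478). SGK1 rose (1.78) and HSPA4L fell (-1.05). Both metallothioneins tested rose, MT2A by 1.98 and MT1X by 0.82.

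Respiratory genes on the mitochondrial genome fell, since 0 of the 13 measured rose, 11 fell and 2 did not pass the test (median -0.40, camera adjusted p = 7.8e-05, but adjusted p = 0.124 with an estimated correlation). MT-ATP6 (-0.84) and MT-CYB (-0.49) had the smallest p, and MT-ND1 had 0.06 (adjusted p = 0.37). Of nuclear-encoded subunits, 8 of the 76 measured rose (5 without normoxia replicate 3 or hypoxia replicate 1 or 3), 23 fell and 45 did not pass the test (median -0.06, camera adjusted p = 0.307). NDUFB5 (-0.64) and ATP5MC1 (-0.49) fell and NDUFC2 (0.62) and ATP5F1D (0.32) rose. In the tricarboxylic acid cycle, 4 of the 23 measured rose, 12 fell and 7 did not pass the test (median -0.19, camera adjusted p = 0.0912), and OGDH (-1.41) and ACO2 (-0.87) were among those that fell. Of fatty acid and lipid storage genes, 5 of the 18 measured rose (2 without normoxia replicate 1 or 2 or hypoxia replicate 2), 8 fell and 5 did not pass the test, or 5 up and 9 down adjusted over the list alone (median -0.18, camera adjusted p = 0.00377, but adjusted p = 0.0635 with an estimated correlation). The droplet proteins PLIN2 (0.67) and HILPDA (0.48) rose, and ACACA (-1.27) and SCD (-0.98), which make and desaturate fatty acids, fell. Among cholesterol genes, 3 of the 24 measured rose, 11 fell and 10 did not pass the test (median -0.14, camera adjusted p = 0.011, but adjusted p = 0.141 with an estimated correlation). TM7SF2 (-2.93) and LDLR (-1.04) fell and SC5D (0.55) rose.

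Of replication-dependent histones, 4 of the 20 measured rose (2 without normoxia replicate 3 or hypoxia replicate 1), 10 fell and 6 did not pass the test (median -0.63, camera adjusted p = 0.0258, but adjusted p = 0.286 with an estimated correlation). HIST1H2AC (-2.28) and HIST1H2BD (-2.41) fell and HIST1H2BN (1.60) rose. In DNA replication, 8 of the 51 measured rose, 22 fell and 21 did not pass the test, or 8 up and 23 down adjusted over the list alone (median -0.16, camera adjusted p = 0.114). RPA1 (-0.64) fell and CCNE1 (0.83) rose. In mitosis, 7 of the 42 measured rose (4 without hypoxia replicate 3), 11 fell and 24 did not pass the test (median -0.09, camera adjusted p = 0.343). CCNB1 (-0.66) fell and KIF23 (0.44) rose. For histone acylation writers and erasers, 3 of the 29 measured rose, 11 fell and 15 did not pass the test, or 4 up and 11 down adjusted over the list alone (median -0.14, camera adjusted p = 0.307), and HDAC1 fell (-0.89). For lysine demethylases, 3 of the 20 measured rose, 7 fell and 10 did not pass the test (median -0.06, camera adjusted p = 0.643). KDM3A (1.41) rose and KDM1B (-1.72) fell. Among p53 targets, 6 of the 21 measured rose, 5 fell and 10 did not pass the test (median 0.09, camera adjusted p = 0.307). GADD45A (1.22) rose and TP53I3 (-1.15) fell. Of cytosolic ribosomal proteins, 27 of the 78 measured rose (11 without hypoxia replicate 3, 17 without normoxia replicate 1), 4 fell (1 without normoxia replicate 2 or 3 or hypoxia replicate 1, 2 without hypoxia replicate 2) and 47 did not pass the test, or 19 up and 2 down adjusted over the list alone (median 0.11, camera adjusted p = 0.0912). RPL11 (0.27) rose and RPS26 (-0.29) fell.

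Placental cell type markers gave no call as lists. Trophoblast identity showed 7 of 12 up and 3 down (1 without normoxia replicate 1 or 3 or hypoxia replicate 2 or 3), or 7 up and 4 down adjusted over the list alone (median 0.25, camera adjusted p = 0.208). ITGA6 (0.75) had more and KRT18 (-0.32) fewer transcripts. Extravillous markers showed 4 of 13 up and 3 down, or 4 up and 4 down adjusted over the list alone (median 0.09, mean -0.08, test upward; camera adjusted p = 0.492), where MCAM (-0.96) fell. Syncytiotrophoblast markers showed 4 of 13 up and 4 down, or 4 up and 6 down adjusted over the list alone (median -0.03, mean 0.14, test downward; camera adjusted p = 0.795), as CGB8 (2.84) and CGB7 (1.68) of chorionic gonadotropin rose and TFPI2 (-0.56) and PSG1 (-2.07) fell. Stromal and fibroblast markers showed 5 of 11 up and 5 down (median -0.35, camera adjusted p = 0.613). NR2F2 (0.99) and TAGLN (0.85) had more and THY1 (-0.98) fewer transcripts. Endothelial markers showed 2 of 5 up and 0 down, or 3 up and 0 down adjusted over the list alone (median 0.62, camera adjusted p = 0.153). These were ROBO4 (1.18) and TIE1 (0.62), and neither of the 2 leukocyte markers passed (by edgeR 0 at an unadjusted p below 0.05 and 0 called by DESeq2). Epithelial and junction genes showed 5 of 13 up and 6 down, or 6 up and 6 down adjusted over the list alone (median 0.20, mean -0.02, test upward; camera adjusted p = 0.583). LAMB3 (1.31) had more and CLDN1 (-0.92) fewer transcripts. The pH and proton list showed 5 of 18 up and 5 down (3 without normoxia replicate 2), or 6 up and 6 down adjusted over the list alone (median 0.07, camera adjusted p = 0.245), where SLC4A2 (-0.39) fell, and autophagy 6 of 19 up and 4 down (median 0.01, camera adjusted p = 0.079), where BNIP3 (2.31) and BNIP3L (1.91) rose and SQSTM1 (-1.03) fell.

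As lists, 14 of 37 passed at the preset correlation in hypoxia, 7 up and 7 down. With an estimated correlation 6 did, the HIF targets, glycolysis, matrix, angiogenic, NRF2 and interferon lists.

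**Figure D2:**
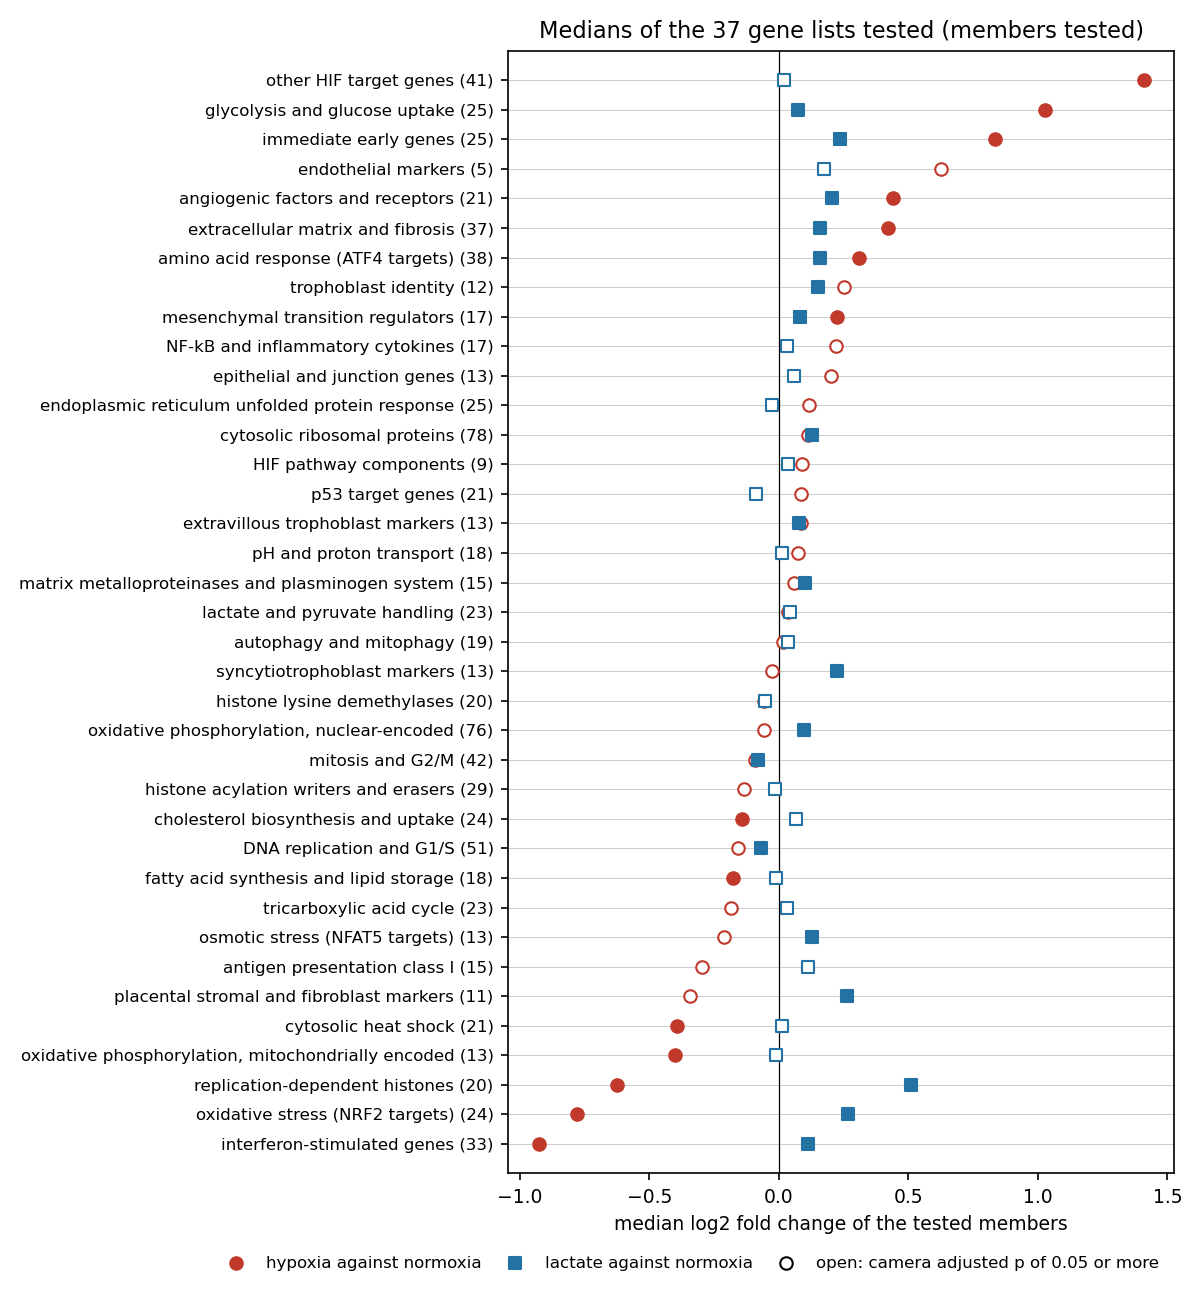
Median log2 fold change against normoxia of the tested members of each of 37 gene lists, with circles for hypoxia and squares for lactate; filled symbols have a camera adjusted p below 0.05, and the number of members tested stands after each name. HIF targets and glycolysis lie at 1.41 and 1.03 in hypoxia and at 0.02 and 0.07 in lactate, while NRF2 targets lie at -0.78 and 0.27.

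Lactate was compared with normoxia to show what added lactate, the end product of glycolysis, changes in these cells. Its effects were small in size and mostly upward, in lists of NRF2, ATF4 and NFAT5 targets, matrix, immediate early genes and histones among others. ACTC1, the cardiac actin, rose from 3.94 ± 0.467 CPM to 16.5 ± 1.94 CPM, and SERPINE1 from 100.1 ± 2.98 CPM to 189 ± 2.04 CPM. AKR1C1, an aldo-keto reductase under NRF2, rose from 8.64 ± 0.563 CPM to 35.3 ± 4.59 CPM, and NQO1 from 346 ± 7.88 CPM to 526 ± 21.7 CPM. DUSP1, a phosphatase that ends MAP kinase signals, rose from 69.6 ± 2.58 CPM to 126 ± 3.01 CPM, while VEGFA, at 23.5 ± 2.11 CPM, did not pass the test.

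A total of 442 genes (2.79% of those tested) passed in lactate, 351 higher and 91 lower, and 29 of them changed at least 2-fold, 25 up and 4 down. The 3 libraries of each group did not overlap for 3147 genes (19.9%), against a chance share of 10%. The number of calls leaned on single libraries. It was 268, 199 and 188 without normoxia replicates 1, 2 and 3, and 272, 830 and 512 without lactate replicates 1, 2 and 3. Of the genes called without lactate replicate 2, 61.3% were higher, against 79.4% with all libraries.

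Among protein-coding genes that met the naming rule, with at least 5 CPM and no overlap between groups, the largest rises were those of ACTC1 (2.07), AKR1C1 (2.03), CRYAB (1.36), KRT34 (1.27) and KISS1 (1.12), as log2 fold changes. CRYAB is a small heat shock protein, KRT34 a hair keratin and KISS1 the kisspeptin precursor made by trophoblast. CXCL12, TMEM158, SLC6A9, NTN4 and SERPINE1 followed, with log2 fold changes of 1.08, 1.06, 1.05, 1.00 and 0.92. ACTC1 (log2 fold change 2.07, SE 0.14, adjusted p = 8.5e-10) and SERPINE1 (log2 fold change 0.92, SE 0.07, adjusted p = 3.22e-08) passed with any of the 6 libraries left out. By the same rule the largest falls were those of COL9A3 (-0.97), PLIN4 (-0.76), FER1L5 (-0.65), BCL3 (-0.65), SYNPO (-0.65) and CCNE2 (-0.64). BCL3 is a coactivator of NF-kB and SYNPO binds actin. AMH, AGER, QRICH2 and XPNPEP3 fell with log2 fold changes of -0.62, -0.59, -0.59 and -0.57. Some of these falls were lost on leaving out a library, namely PLIN4 (adjusted p up to 0.132 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 3), FER1L5 (adjusted p up to 0.14 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 3), AGER (adjusted p up to 0.0745 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 3), CCNE2 (adjusted p = 0.0696 without normoxia replicate 2) and QRICH2 (adjusted p up to 0.0849 without normoxia replicate 3 or lactate replicate 1).

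Among NRF2 targets, 11 of the 24 measured rose (5 without normoxia replicate 2 or 3, 7 without lactate replicate 1), 0 fell and 13 did not pass the test, or 17 up and 0 down adjusted over the list alone (median 0.27, camera adjusted p = 4.72e-21). Unless given, counts adjusted over the list alone were again the same as those over all genes. AKR1C1 (log2 fold change 2.03, SE 0.11, adjusted p = 3.06e-11), NQO1 (log2 fold change 0.60, SE 0.06, adjusted p = 8.17e-07), AKR1C3, AKR1C2, TXNRD1, FTL, FTH1, HMOX1, ME1, PRDX1 and SLC7A11 were the members that rose. Of the ATF4 targets, 8 of the 38 measured rose (5 without normoxia replicate 1, 2 or 3), 1 fell and 29 did not pass the test, or 14 up and 1 down adjusted over the list alone (median 0.16, camera adjusted p = 2.53e-08). The glycine carrier SLC6A9 (1.05) and the neutral amino acid carrier SLC38A2 (0.57) rose, and the factor ATF5 fell (-0.43). Among osmotic stress targets of NFAT5, 6 of the 13 measured rose, 0 fell and 7 did not pass the test (median 0.13, camera adjusted p = 9.2e-07), and the members that rose were AKR1B1, S100A4, SGK1, SLC38A2, SLC5A3 and SLC6A6. SGK1, a kinase that raises sodium uptake, rose by 0.57. CRYAB, at 1.36, was the cytosolic heat shock gene that rose, and in that list 1 of the 21 measured rose (2 without lactate replicate 2), 0 fell and 20 did not pass the test (median 0.01, camera adjusted p = 0.082).

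Matrix genes were the other main group. Of the matrix and fibrosis list, 14 of the 37 measured rose, 0 fell and 23 did not pass the test, or 18 up and 0 down adjusted over the list alone (median 0.16, camera adjusted p = 1.99e-16). SERPINE1 (0.92), the adhesion proteins CYR61 (0.61) and CTGF (0.80), COL1A2 (1.54) and TAGLN (0.38) rose, and FN1 went from 1135 ± 40.7 CPM to 1456 ± 182 CPM (adjusted p = 0.00627). COL1A2, and S100A4, PLAU and DUSP6 below, changed more than some genes listed above as largest rises or falls. They did not meet that rule, so each had a mean under 5 CPM or groups that overlapped. In the metalloproteinase and plasminogen list, 5 of the 15 measured rose, 1 fell (0 without normoxia replicate 3 or lactate replicate 3) and 9 did not pass the test (median 0.10, camera adjusted p = 5.44e-08). The protease inhibitor SERPINE2 (0.70), PLAT, ADAMTS1 and SERPINB2 rose beside SERPINE1, and PLAU, the urokinase, fell (-1.09; adjusted p up to 0.0908 without normoxia replicate 3 or lactate replicate 3). Of angiogenic factors, 6 of the 21 measured rose (2 without normoxia replicate 2 or 3, 3 without normoxia replicate 1), 0 fell and 15 did not pass the test, or 8 up and 0 down adjusted over the list alone (median 0.21, camera adjusted p = 6.78e-07). The vasoconstrictor EDN1 (0.89) and EPHA2 (0.40) rose, whereas PGF had 0.27 (adjusted p = 0.643) and ENG 0.21 (adjusted p = 0.162). Of immediate early genes, 8 of the 25 measured rose (4 without normoxia replicate 3, 5 without normoxia replicate 2), 1 fell (0 without normoxia replicate 3) and 16 did not pass the test, or 14 up and 1 down adjusted over the list alone (median 0.24, camera adjusted p = 6.68e-11), with DUSP1 (0.85) and JUN (0.61) having the smallest p, and DUSP6 lower (-0.99; adjusted p = 0.0511 without normoxia replicate 3).

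Mesenchymal regulators passed near the threshold, where 2 of the 17 measured rose (1 without normoxia replicate 1, 2 or 3 or lactate replicate 1), 1 fell (0 without normoxia replicate 1 or 3 or lactate replicate 1) and 14 did not pass the test, or 3 up and 1 down adjusted over the list alone (median 0.08, camera adjusted p = 0.049, but adjusted p = 0.192 with an estimated correlation). The list was not past the test without normoxia replicate 1 (adjusted p = 0.0611), normoxia replicate 2 (0.0834), lactate replicate 1 (0.0746) or lactate replicate 3 (0.126). S100A4 (1.15) and TWIST2 (0.39; adjusted p up to 0.0938 without normoxia replicate 1, 2 or 3 or lactate replicate 1) rose and SMAD3 (-0.31; adjusted p up to 0.164 without normoxia replicate 1 or 3 or lactate replicate 1) fell. Interferon-stimulated genes were also near the threshold, where 3 of the 33 measured rose (1 without normoxia replicate 1, 2 or 3 or lactate replicate 1), 0 fell and 30 did not pass the test, or 4 up and 0 down adjusted over the list alone (median 0.11, camera adjusted p = 0.0498, but adjusted p = 0.121 with an estimated correlation). That list was not past it without normoxia replicate 1 (0.0611), lactate replicate 1 (0.102) or lactate replicate 3 (0.117), and also not when scaled by RLE (0.0508). The members that rose were GBP1 (0.59), USP18 and IFI44 (0.70; adjusted p up to 0.209 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 3). Class I antigen presentation had 0 of 15 up (1 without lactate replicate 3) and 0 down (median 0.11, camera adjusted p = 0.131; with edgeR 5 at an unadjusted p below 0.05 and 1 called by DESeq2). NF-kB and inflammatory cytokines had 2 of 17 up (0 without normoxia replicate 2 or 3 or lactate replicate 1) and 0 down, or 3 up and 0 down adjusted over the list alone (median 0.03, camera adjusted p = 0.14). They were IER3 (0.35; adjusted p up to 0.138 without normoxia replicate 2 or 3 or lactate replicate 1) and IL11 (0.33; adjusted p up to 0.23 without normoxia replicate 2 or 3 or lactate replicate 1).

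Of replication-dependent histones, 7 of the 20 measured rose (4 without lactate replicate 1), 0 fell and 13 did not pass the test, or 10 up and 0 down adjusted over the list alone (median 0.51, camera adjusted p = 3.37e-11). HIST1H2AC rose by 0.74 and HIST1H2BK by 0.72. DNA replication had 0 of 51 up and 2 down (0 without normoxia replicate 2, 1 without normoxia replicate 1 or 3 or lactate replicate 1, 4 without lactate replicate 2; median -0.07, camera adjusted p = 0.00185, but adjusted p = 0.231 with an estimated correlation). These were the cyclin CCNE2 (-0.64; adjusted p = 0.0696 without normoxia replicate 2) and DHFR (-0.31; adjusted p up to 0.159 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 2). Mitosis had 0 of 42 up and 1 down (0 without normoxia replicate 2 or 3, 2 without lactate replicate 2, 4 without lactate replicate 3), or 0 up and 4 down adjusted over the list alone (median -0.08, camera adjusted p = 0.000144, but adjusted p = 0.283 with an estimated correlation). The member was HMMR (-0.38; adjusted p up to 0.209 without normoxia replicate 2 or 3). Ribosomal proteins had 3 of 78 up (0 without normoxia replicate 1 or 2, 7 without lactate replicate 3, 15 without lactate replicate 2) and 0 down, or 16 up and 0 down adjusted over the list alone (median 0.13, camera adjusted p = 2.17e-13, but adjusted p = 0.231 with an estimated correlation). They were RPS23, RPL41 (0.24; adjusted p up to 0.238 without normoxia replicate 1, 2 or 3 or lactate replicate 1) and RPS27 (0.32; adjusted p up to 0.247 without normoxia replicate 1 or 2 or lactate replicate 2 or 3). Histone acylation writers and erasers had 0 of 29 up (1 without lactate replicate 2) and 0 down (2 without lactate replicate 2), or 1 up and 0 down adjusted over the list alone (median -0.02, camera adjusted p = 0.352; with edgeR 6 at an unadjusted p below 0.05 and 1 called by DESeq2). Lysine demethylases had 0 of 20 up (1 without lactate replicate 2) and 1 down (0 without normoxia replicate 1, 2 or 3 or lactate replicate 1), or 1 up and 2 down adjusted over the list alone (median -0.05, camera adjusted p = 0.191). The member was KDM3A (-0.33; adjusted p up to 0.138 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 2). The p53 targets had 1 of 21 up and 0 down, or 2 up and 0 down adjusted over the list alone (median -0.09, camera adjusted p = 0.738). The member was GADD45A (0.38), and MT2A fell (-0.33; adjusted p up to 0.122 without normoxia replicate 2 or 3) while MT1X had -0.50 (adjusted p = 0.297), so that 1 of the 2 metallothioneins was lower, or 2 adjusted over the list alone.

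Genes that answer to low oxygen moved little in lactate. HIF targets outside glycolysis had 3 of 41 up (5 without lactate replicate 2) and 2 down (0 without normoxia replicate 2, 1 without normoxia replicate 1 or 3), or 4 up and 3 down adjusted over the list alone (median 0.02, mean -0.00299, test upward; camera adjusted p = 0.462). IGFBP3 (0.68), LOX (0.41) and NDRG1 rose, and BHLHE40 (-0.44; adjusted p = 0.078 without normoxia replicate 2) and KDM3A (-0.33; adjusted p up to 0.138 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 2) fell. HIF1A had 0.14 (SE 0.09, adjusted p = 0.454), EPAS1 0.26 (0.0637), VEGFA 0.18 (0.427), CA9 -1.16 (0.234) and SLC2A1 0.12 (0.413). HIF pathway components had 1 of 9 up (2 without lactate replicate 1) and 0 down, or 2 up and 1 down adjusted over the list alone (median 0.03, camera adjusted p = 0.167). The member was CITED2 (0.56), and EP300 had -0.26 (0.217). Glycolysis had 2 of 25 up (1 without normoxia replicate 1, 2 or 3 or lactate replicate 1, 4 without lactate replicate 2) and 0 down (1 without lactate replicate 3), or 4 up and 1 down adjusted over the list alone (median 0.07, camera adjusted p = 0.00254, but adjusted p = 0.231 with an estimated correlation). The members were HK1 (0.39) and LDHA (0.22; adjusted p up to 0.132 without normoxia replicate 1, 2 or 3 or lactate replicate 1). PDK1 had -0.33 (0.0665). Lactate and pyruvate handling had 2 of 23 up (1 without normoxia replicate 1, 2 or 3 or lactate replicate 1) and 0 down (1 without lactate replicate 3), or 2 up and 1 down adjusted over the list alone (median 0.04, camera adjusted p = 0.188). These were LDHA and PCK2 (0.41). The carriers SLC16A1 (0.07; 0.673) and SLC16A3 (0.19; 0.216) and LDHB (0.22; 0.32) did not pass.

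Nuclear-encoded respiratory subunits had 0 of 76 up (1 without lactate replicate 3, 3 without lactate replicate 2) and 0 down (median 0.10, camera adjusted p = 8.67e-05, but adjusted p = 0.38 with an estimated correlation; with edgeR 17 at an unadjusted p below 0.05 and 4 called by DESeq2). Mitochondrially encoded ones had 0 of 13 up (1 without lactate replicate 2) and 0 down (median -0.01, mean -0.01, test upward; camera adjusted p = 0.879; with edgeR 2 at an unadjusted p below 0.05 and 1 called by DESeq2). The tricarboxylic acid cycle had 0 of 23 up (1 without lactate replicate 2) and 0 down (median 0.03, camera adjusted p = 0.354; with edgeR 2 at an unadjusted p below 0.05 and 0 called by DESeq2). Cholesterol genes had 2 of 24 up (0 without normoxia replicate 1, 2 or 3 or lactate replicate 1) and 0 down, or 5 up and 0 down adjusted over the list alone (median 0.07, camera adjusted p = 0.0516). These were FDFT1 (0.30; adjusted p up to 0.0892 without normoxia replicate 1, 2 or 3 or lactate replicate 1) and STARD4 (0.32; adjusted p up to 0.205 without normoxia replicate 1, 2 or 3 or lactate replicate 1 or 3). Fatty acid genes had 0 of 18 up and 0 down (2 without lactate replicate 2; median -0.01, camera adjusted p = 0.41; with edgeR 3 at an unadjusted p below 0.05 and 0 called by DESeq2). The unfolded protein response had 0 of 25 up and 1 down (0 without normoxia replicate 2 or 3 or lactate replicate 1, 2 without lactate replicate 2; median -0.03, camera adjusted p = 0.131). The member was SEL1L (-0.28; adjusted p up to 0.194 without normoxia replicate 2 or 3 or lactate replicate 1). The pH and proton list had 1 of 18 up (0 without normoxia replicate 1 or 2 or lactate replicate 1) and 1 down (0 without normoxia replicate 1, 2 or 3 or lactate replicate 1, 2 or 3; median 0.01, mean -0.09, test upward; camera adjusted p = 0.903), with ASIC1 up (0.43; adjusted p up to 0.122 without normoxia replicate 1 or 2 or lactate replicate 1) and SLC4A8 down (-0.51; adjusted p up to 0.238 without normoxia replicate 1, 2 or 3 or lactate replicate 1, 2 or 3). Autophagy had 3 of 19 up (1 without normoxia replicate 2 or 3) and 0 down, or 4 up and 0 down adjusted over the list alone (median 0.04, camera adjusted p = 0.219). These were PINK1 (0.57), OPTN and GABARAPL1 (0.35; adjusted p up to 0.0789 without normoxia replicate 2 or 3).

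Syncytiotrophoblast, extravillous, stromal and trophoblast identity markers passed upward as lists, though most members of each did not pass the test. Of the members that rose, SERPINE1, SERPINE2, COL1A2 and TAGLN also belong to the matrix or protease lists above. Syncytiotrophoblast markers had 5 of 13 up (3 without normoxia replicate 3) and 0 down (median 0.23, camera adjusted p = 4.39e-06). They were KISS1 (1.12), the protease inhibitor TFPI2 (0.54), PSG1, PSG4 and PSG5. Extravillous markers had 2 of 13 up and 0 down, or 3 up and 0 down adjusted over the list alone (median 0.08, camera adjusted p = 9.36e-06). They were SERPINE1 and SERPINE2. Stromal markers had 3 of 11 up and 0 down, or 5 up and 0 down adjusted over the list alone (median 0.26, camera adjusted p = 1.49e-06). They were COL1A2, TAGLN and the receptor NR2F1. Trophoblast identity had 1 of 12 up (0 without normoxia replicate 1, 2 or 3 or lactate replicate 1, 2 without lactate replicate 3) and 0 down, or 2 up and 0 down adjusted over the list alone (median 0.15, camera adjusted p = 0.00277). The member was KRT18 (0.26; adjusted p up to 0.147 without normoxia replicate 1, 2 or 3 or lactate replicate 1). Endothelial markers had 0 of 5 up and 0 down, or 1 up and 0 down adjusted over the list alone (median 0.18, camera adjusted p = 0.155; with edgeR 1 at an unadjusted p below 0.05 and 0 called by DESeq2). Epithelial and junction genes had 1 of 13 up and 0 down (1 without lactate replicate 2; median 0.06, camera adjusted p = 0.229). The member was CLDN1 (0.84). Leukocyte markers had 0 of 2 up and 0 down (by edgeR 0 at an unadjusted p below 0.05 and 0 called by DESeq2). Of 37 lists, 19 passed at the preset correlation, 17 up and 2 down, and 12 with an estimated correlation.

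**Figure D3:**
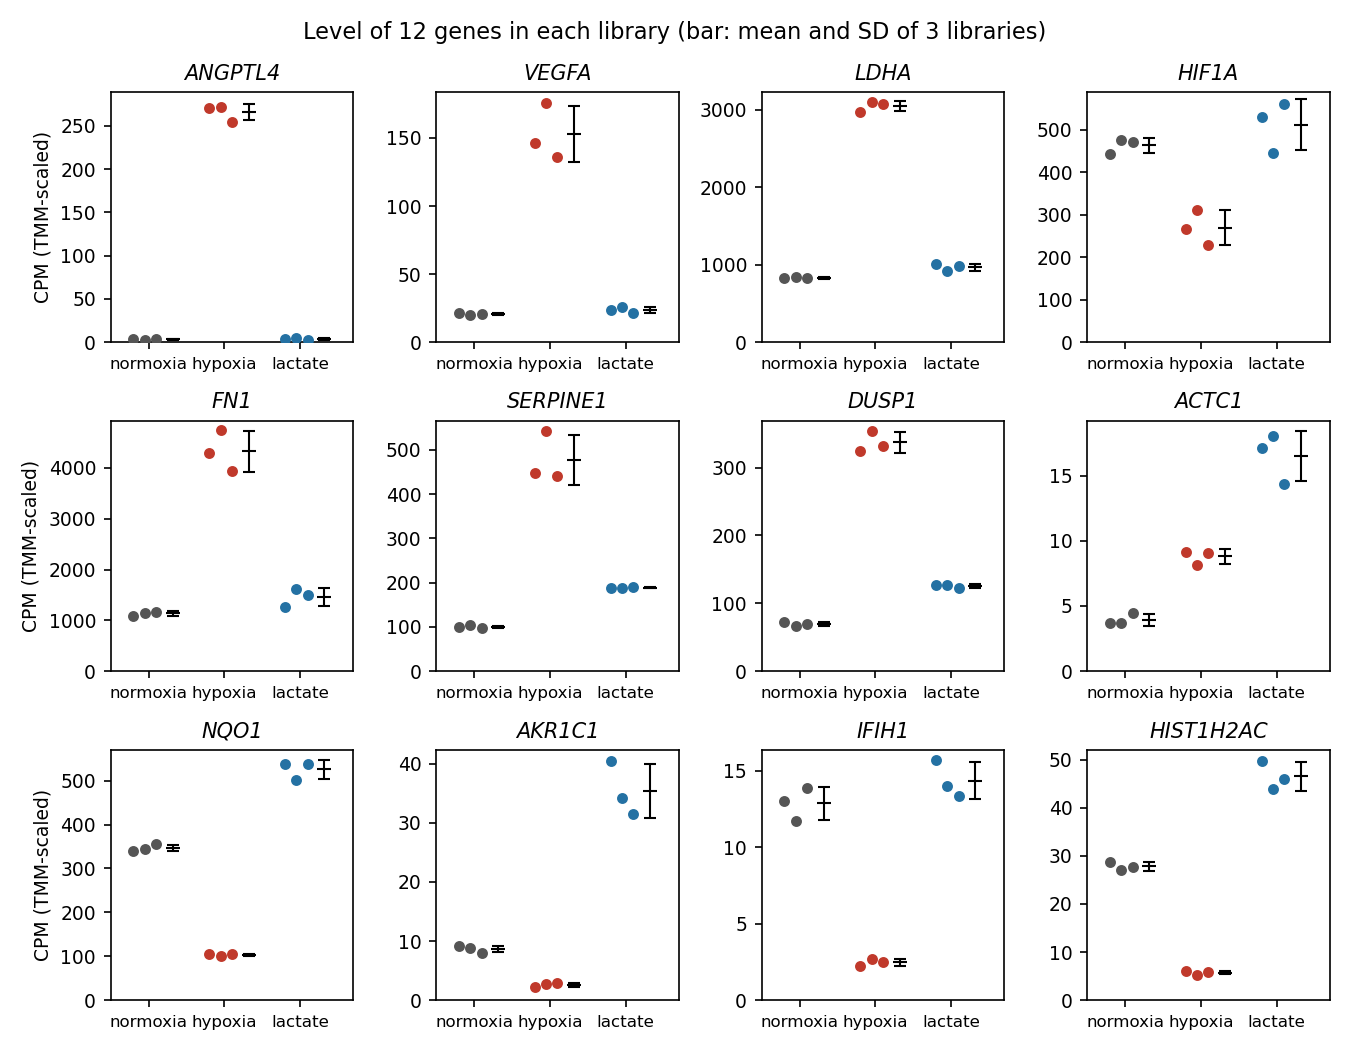
Level in CPM of 12 named genes, on linear axes that start at 0, in the 9 libraries, with a panel for each gene; points are libraries, and the bar is the mean with SD of 3 libraries. ANGPTL4, VEGFA and LDHA rise in hypoxia, FN1, SERPINE1 and DUSP1 rise in both treatments, and NQO1, AKR1C1 and HIST1H2AC fall in hypoxia and rise in lactate.

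Hypoxia was compared with lactate to show how far the treatments differ. Cells in hypoxia had more transcripts for glycolysis, HIF targets and vessel growth and fewer for oxidant defence and interferon response than cells given lactate. Histones and heat shock genes were lower too, but these calls did not hold with an estimated correlation (adjusted p = 0.111 and 0.108). CA9 stood at 28.8 ± 3.12 CPM in hypoxia and 0.233 ± 0.0566 CPM, near the count floor, in lactate. PDK1, a kinase that inhibits pyruvate dehydrogenase, stood at 138 ± 5.59 CPM and 15.4 ± 1.78 CPM. NQO1 stood at 103 ± 3.02 CPM and 526 ± 21.7 CPM, and AKR1C1 at 2.6 ± 0.373 CPM and 35.3 ± 4.59 CPM. In all, 8205 genes differed, 3994 higher and 4211 lower in hypoxia, with 940 and 929 of them by at least 2-fold. The libraries of the groups did not overlap for 8656 genes (54.7%), where chance gives 10%.

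By the naming rule the largest excesses in hypoxia were those of CA9 (6.90), ANGPTL4 (6.21), INHBB (5.85), FAM83A (5.45) and TGFBI (4.68), and the largest deficits those of IGFN1 (-5.04), PIR (-4.14), ARG2 (-4.14), ZNF467 (-3.98) and PALM3 (-3.90). Among HIF targets, 34 of the 41 measured were higher in hypoxia, 1 was lower (0 without hypoxia replicate 2 or 3 or lactate replicate 2) and 6 did not pass the test, or 36 up and 1 down adjusted over the list alone (median 1.41, camera adjusted p = 4.62e-79). ANGPTL4 (6.21) and NDRG1 (3.79) led it. The member lower in hypoxia was PLOD1 (-0.21; adjusted p up to 0.128 without hypoxia replicate 2 or 3 or lactate replicate 2). Of glycolysis genes, 24 of the 25 measured were higher in hypoxia, 1 was lower and 0 did not pass the test (median 0.95, camera adjusted p = 3.23e-42), with PGK1 (1.86) and PDK1 (3.16) having the smallest p and PFKM (-0.79) lower. VEGFA differed by 2.704, SLC2A1 by 2.03 and LDHA by 1.66, while HIF1A was lower (-0.93). Of angiogenic factors, 10 of the 21 measured were higher in hypoxia, 5 were lower (3 without hypoxia replicate 2) and 6 did not pass the test (median 0.23, camera adjusted p = 1e-05). PGF (1.84) had more and NRP1 (-1.83) fewer transcripts. Of the matrix list, 21 of the 37 measured were higher in hypoxia, 10 were lower and 6 did not pass the test, or 22 up and 10 down adjusted over the list alone (median 0.30, camera adjusted p = 0.00315, but adjusted p = 0.129 with an estimated correlation). FN1 (1.57) and SERPINE1 (1.34) had more and COL3A1 (-3.21) fewer transcripts. Immediate early genes showed the same lean, as 14 of the 25 measured were higher in hypoxia, 6 were lower and 5 did not pass the test (median 0.33, camera adjusted p = 2.44e-05, but adjusted p = 0.189 with an estimated correlation). So did mesenchymal regulators, where 8 of the 17 measured were higher in hypoxia, 5 were lower and 4 did not pass the test (median 0.23, camera adjusted p = 0.022, but adjusted p = 0.157 with an estimated correlation).

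Of NRF2 targets, 0 of the 24 measured were higher in hypoxia, 23 were lower and 1 did not pass the test (median -1.11, camera adjusted p = 1.5e-27). NQO1 (-2.35) and AKR1C1 (-3.76) led it. Of interferon-stimulated genes, 0 of the 33 measured were higher in hypoxia, 30 were lower and 3 did not pass the test (median -1.02, camera adjusted p = 6.28e-14). IFIH1 (-2.53) and PSMB9 (-3.22) led it. Of replication-dependent histones, 1 of the 20 measured was higher in hypoxia (0 without hypoxia replicate 1 or 2 or lactate replicate 1, 2 or 3), 14 were lower and 5 did not pass the test, or 1 up and 15 down adjusted over the list alone (median -1.001, camera adjusted p = 1.53e-05, but adjusted p = 0.111 with an estimated correlation), with HIST1H2AC (-3.02) and HIST1H2BD (-3.07) lower. Of heat shock genes, 2 of the 21 measured were higher in hypoxia (0 without hypoxia replicate 2 or 3 or lactate replicate 2, 1 without lactate replicate 1 or 3), 17 were lower and 2 did not pass the test, or 2 up and 18 down adjusted over the list alone (median -0.43, camera adjusted p = 9.52e-08, but adjusted p = 0.108 with an estimated correlation), with CRYAB (-2.80) and HSPA1B (-1.13) lower. Cholesterol genes leaned the same way, since 3 of the 24 measured were higher in hypoxia, 12 were lower and 9 did not pass the test, or 3 up and 13 down adjusted over the list alone (median -0.26, camera adjusted p = 0.00151, but adjusted p = 0.108 with an estimated correlation). TM7SF2 (-2.86) and DHCR24 (-0.79) were lower. In fatty acid synthesis, 5 of the 18 measured were higher in hypoxia (3 without hypoxia replicate 1 or 2 or lactate replicate 1), 9 were lower and 4 did not pass the test, or 5 up and 10 down adjusted over the list alone (median -0.22, camera adjusted p = 0.0136, but adjusted p = 0.108 with an estimated correlation). SCD (-1.05) was lower and PLIN2 (0.52) higher. Mitochondrially encoded respiratory genes were lower, as 0 of the 13 measured were higher in hypoxia, 12 were lower and 1 did not pass the test (median -0.43, camera adjusted p = 0.000103, but adjusted p = 0.14 with an estimated correlation). Of nuclear-encoded ones, 6 of the 76 measured were higher in hypoxia (3 without hypoxia replicate 1), 34 were lower and 36 did not pass the test (median -0.15, camera adjusted p = 0.029, but adjusted p = 0.662 with an estimated correlation). That list did not pass without hypoxia replicate 2 (adjusted p = 0.103) or lactate replicate 1 (0.0885).

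The other 23 lists did not pass between hypoxia and lactate, and 5 of the 14 that did also passed with an estimated correlation. In some the median, mean and direction of the test differed in sign. These were lactate and pyruvate handling (median -0.11, mean 0.01, test upward), metalloproteinases and plasminogen (median -0.13, mean -0.18, test upward), NFAT5 targets (median -0.17, mean 0.31, test downward), NF-kB and cytokines (median -0.00266, mean 0.33, test upward), epithelial and junction genes (median -0.30, mean -0.09, test upward), lysine demethylases (median -0.07, mean -0.0042, test upward) and autophagy (median -0.03, mean 0.14, test upward). PC (-0.96) and SLC16A7 (-0.83) were lower in hypoxia, and the osmolyte carrier SLC5A3 (-1.38) as well. SLC16A3 (0.62), KDM3A (1.74) and BNIP3 (2.28) were higher. LDHB had -0.19 (adjusted p = 0.149), SLC16A1 -0.11 (0.189), EPAS1 -0.18 (0.0577) and EP300 0.07 (0.596). ENG had 0.23 (0.0114; adjusted p up to 0.0774 without hypoxia replicate 1 or lactate replicate 3).

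Genes changed by both treatments were counted to show what hypoxia and lactate share. With log2 fold changes in hypoxia and then in lactate, the shared rises picked by the naming rule began with KRT34 (1.31 and 1.27), ACTC1 (1.16 and 2.07), CXCL12 (1.16 and 1.08), TMEM158 (2.49 and 1.06) and SERPINE1 (2.25 and 0.92). They went on with ARL4C (1.02 and 0.90), EDN1 (2.26 and 0.89), NR2F1 (1.23 and 0.86), DUSP1 (2.28 and 0.85) and CTGF (1.73 and 0.80). ARL4C is a small GTPase of the cell edge, NR2F1 an orphan nuclear receptor and TMEM158 a membrane protein induced by RAS. In opposite directions the rule picked AKR1C1 (-1.73 and 2.03), CRYAB (-1.44 and 1.36), MLLT11 (-1.73 and 0.90), CASC10 (-2.28 and 0.86) and CLDN1 (-0.92 and 0.84). CASC10 did not pass in lactate without some libraries (adjusted p up to 0.0743 without normoxia replicate 1 or 3 or lactate replicate 1).

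In counts, 141 genes rose in both treatments, against 82.0 for independent lists, and 32 fell in both, against 23.0. In opposite directions, 28 rose in hypoxia and fell in lactate, against 21.3, and 131 fell in hypoxia and rose in lactate, against 88.7. These counts leaned on single libraries, and the excess over independence did not hold throughout. Genes higher in hypoxia and lower in lactate numbered 8 against 8.24 without normoxia replicate 1, 3 against 5.37 without normoxia replicate 2 and 4 against 3.36 without normoxia replicate 3. They numbered 16 without hypoxia replicate 3, 10 without lactate replicate 1 and 99 without lactate replicate 2, against 12.4, 8.83 and 79.7. Genes lower in both numbered 14, 14 and 7 without normoxia replicates 1, 2 and 3, 19 without hypoxia replicate 3, 10 without lactate replicate 1 and 114 without lactate replicate 2. The expectations for these were 8.90, 5.93, 3.68, 13.8, 9.37 and 87.7. Genes higher in both fell to 76 without normoxia replicate 2 or 3, against 34.2 and 33.8. Genes lower in hypoxia and higher in lactate fell to 65, 51 and 53 without normoxia replicates 1, 2 and 3 and to 78 without lactate replicate 1, against 50.7, 37.8, 37.0 and 57.7. Only genes higher in hypoxia and lower in lactate fell below independence with a library left out. The expectation for independent lists takes every gene as equally likely to be called. Genes measured more precisely pass more readily in both comparisons, which alone can give an excess. With all libraries the opposite directions showed an excess too, so the excess does not show a shared response. Of the 351 genes higher in lactate, 141 were higher, 131 lower and 79 not past the test in hypoxia, and of the 91 lower, 28 were higher, 32 lower and 31 not past. The 173 genes changed in the same direction became 90 without normoxia replicate 2, 83 without normoxia replicate 3 and 313 without lactate replicate 2.

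Across genes, the log2 fold changes of the treatments had a Pearson r of 0.0676 and a Spearman rho of 0.0556, and 51.9% had the same sign. Genes are not independent replicates, and both comparisons use the same controls, which alone gives a positive relation. In 30 simulations with unchanged treatments and shared controls, Pearson r averaged 0.487, Spearman rho 0.446 and the same sign 66.4%. Fold changes there held only noise around a shared control, which fixes such values in advance. The broad effect of hypoxia adds variance, which lowers r and sign agreement even where some genes are shared. The lower observed values therefore do not show that the treatments are less alike than unchanged groups. The covariance was 0.0138 against 0.0248 in the simulations, a difference of -0.0110. Simulated levels came from normoxia alone, so genes nearly absent there had noisy fold changes, which can raise the simulated covariance. The simulations gave 0 genes higher in both and 0.0333 lower in both on average, with at most 1. No gene was changed in them, so an overlap near 0 was fixed in advance. It does not show what shared controls do to lists of 7695 and 442 calls.

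**Figure D4:**
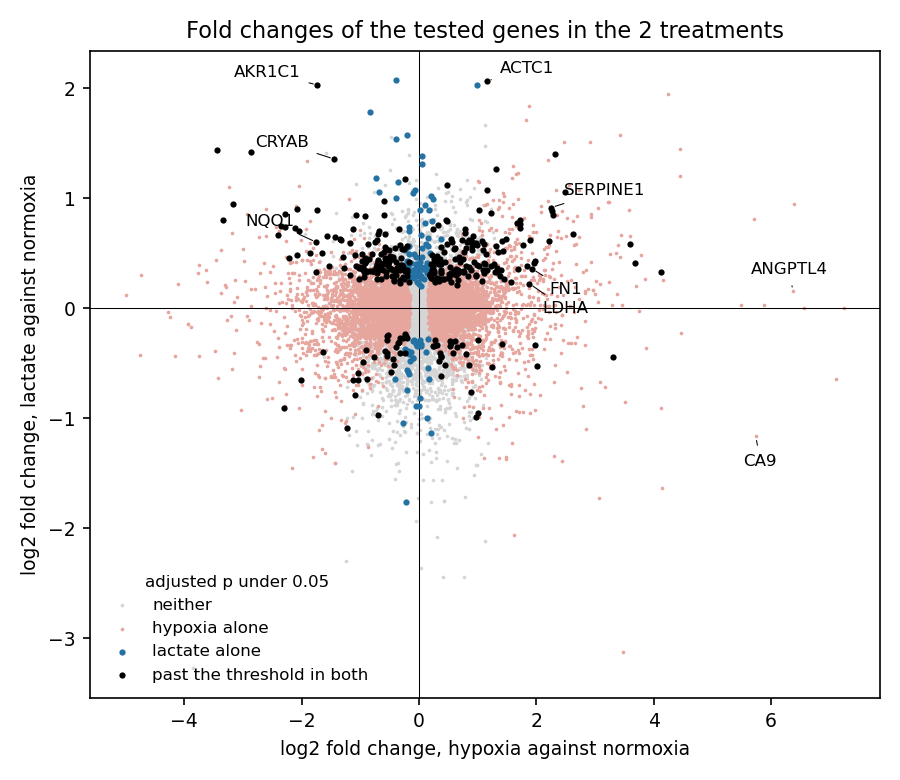
Log2 fold change in lactate against that in hypoxia, both against normoxia, for the 15822 genes tested; each point is a gene, grey where neither comparison passed an adjusted p of 0.05, red for hypoxia alone, blue for lactate alone and black for both. Black points lie in all 4 quadrants, 141 and 32 in the same direction and 28 and 131 in opposite directions.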

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

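No alternative in this part was chosen after its result was seen. Requiring an absolute log2 fold change of at least 1 gave 1600 genes in hypoxia in place of 7695, 29 in lactate in place of 442, 1869 between hypoxia and lactate in place of 8205, and 6 changed in the same direction in both in place of 173, by construction. It left 4 of the 159 genes changed in opposite directions. Other counts in hypoxia were 7716 with RLE scaling, 7018 with DESeq2, 7468 without a filter, 7494 with the stricter filter, 7694 without robust estimation, 7688 without mitochondrially encoded genes and 8360 from the 6 libraries alone. In lactate the same alternatives gave 463, 576, 566, 452, 412, 445 and 375. RLE, DESeq2 and the 6 libraries gave 8233, 7549 and 7619 between hypoxia and lactate. For genes changed in both in the same direction, RLE, DESeq2, no filter, the stricter filter and no robust estimation gave 189, 238, 214, 182 and 169.

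Leaving out each library in turn gave 6710 to 7000 genes in hypoxia, 188 to 830 in lactate, 7362 to 8294 between hypoxia and lactate, and 83 to 313 in both. The lowest counts in lactate and in both came without normoxia replicate 3 and the highest without lactate replicate 2. A fit without a library has fewer libraries to estimate from, which alone can lower a count. The rise to 830 and 313 goes the other way, and the cause was not tested. Lactate replicate 2 was the library most apart from its group by count noise, with a chi-square per degree of freedom of 10.8 and 11.4 to the other lactate libraries, the 11.4 being the highest of the 9 pairs within groups. Pairs of a normoxia and a lactate library had 6.63 to 12.7, so lactate replicate 2 stood about as far from its own group as from normoxia. Lactate replicate 3 was nearer to normoxia replicates 1, 2 and 3 (9.41, 6.63 and 7.07) than to lactate replicate 2.

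Of the 37 lists, the 14 called in hypoxia became 6 with an estimated correlation and 31 with fry. The 19 in lactate became 12 and 20, and the 14 between hypoxia and lactate became 5 and 28. Unlike camera, fry does not compare a list with other genes, and the cause of either shift was not tested. Leaving out libraries gave 14 to 18 lists in hypoxia, 17 to 21 in lactate and 13 to 17 between hypoxia and lactate, and RLE gave 14, 19 and 14.

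The same-numbered libraries of different groups share only a number, with correlations of their deviations from the group mean between -0.0865 and 0.0585. With the number as a replicate block, the counts of genes were 7407 in hypoxia, 347 in lactate, 7903 between hypoxia and lactate and 140 in both. Of genes in both treatments, those lower in both went from 32 to 21, and those higher in hypoxia and lower in lactate from 28 to 18. The counts of lists were 14, 18 and 15, and interferon-stimulated genes in lactate were no longer past the threshold (adjusted p = 0.0529).

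Named genes were followed under RLE scaling, DESeq2, the replicate block and each library of the comparison left out. They were not followed under the other alternatives. Of the named genes, 161 passed in hypoxia and 155 of them under all of those followed. In lactate 73 passed and 45 did so throughout, while 18 of the 97 that did not pass were called under at least 1 of those followed. Between hypoxia and lactate 142 passed and 133 did so throughout. No named gene that passed changed its direction under any of those followed. The smallest change simulated was recovered in 18% of genes in the hypoxia design and 30% in the lactate design, with 50 changed genes at each fold. In real hypoxia 7695 genes passed, which makes the adjusted threshold less strict, so the 18% does not describe that comparison. In lactate, many changes of that size may have gone undetected.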

Other observations

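The tests of small noncoding RNAs in hypoxia, of NRF2 targets without lactate replicate 2 and of other splits of the libraries were planned before their results were seen, and all the other tests in this part were chosen after. Genes of the actin cytoskeleton and of SRF, the factor that answers to free actin, made a further group in lactate. Of 30 measured, 13 rose and 0 fell, with a median log2 fold change of 0.20 (camera adjusted p = 2.74e-17, and 0.0115 with an estimated correlation). In hypoxia 26 rose and 2 fell, with a median of 0.53 (adjusted p = 6.83e-17). The 2 that fell were CNN1 (-0.38) and ACTA2 (-0.52), and neither passed in lactate. Transcripts of SRF itself did not pass in hypoxia (-0.00467, adjusted p = 0.97) or in lactate (0.0452, adjusted p = 0.853). The list was written after ACTC1, TAGLN and CTGF had been seen among the rises. A joint rise of actin and SRF target genes is a candidate explanation for the part that hypoxia and lactate share, and a list found and tested on the same libraries cannot show it.

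Circadian clock genes changed in hypoxia. Of 16 measured, 12 rose and 1 fell, with a median of 0.56 (adjusted p = 7.2e-08, and 0.00686 with an estimated correlation). BHLHE40 (3.30), NFIL3 (2.18) and PER2 (2.07) rose and DBP (-1.45) fell. BHLHE40, BHLHE41 and RORA are also HIF targets in the list used above, so the groups overlap, and no test was run without them. In lactate 0 rose and 1 fell, BHLHE40 (-0.44, adjusted p = 0.00612). The list as a whole had an adjusted p of 0.0471 there, and 0.0877 with an estimated correlation. The 6 tests of these lists were adjusted together. Like the actin list, the clock list was written after values had been seen, so its test on the same libraries cannot show a joint change.

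NRF2 targets fell in hypoxia and rose in lactate. Unusual control libraries shift both treatments the same way, so they cannot be the whole cause of opposite shifts. The direct comparison, in which 23 of the 24 targets were lower in hypoxia than in lactate, follows from those shifts and adds no separate test, and a part played by the controls in either shift stays open. Reads shared among AKR1C paralogs do not carry the rise, since the list without AKR1C1, AKR1C2 and AKR1C3 still passed in lactate (adjusted p = 1.89e-11, and 0.0131 with an estimated correlation). Nor does lactate replicate 2, without which 13 targets rose, against 11 with all libraries. A response of the NRF2 pathway to lactate is a hypothesis found on these libraries, which lactate beside sodium chloride in cells with and without NRF2 would decide. The sodium given with lactate stays open, and no library is labelled as combining lactate with low oxygen.

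Osmolyte genes rose in lactate, with 6 of 13 NFAT5 targets past the test. Sodium lactate at 25 mM also adds sodium, and no library had the sodium without lactate, so lactate and added sodium or osmolarity cannot be told apart here. Unusual normoxia libraries stay open as well. Of the 6 genes, 4 were lower in hypoxia than in lactate and 1 was higher, but genes picked for being high in lactate favour that outcome, and the whole list did not pass in that comparison (camera adjusted p = 0.524).

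Mitochondrial ribosomal RNA rose in both treatments, MT-RNR1 by 1.89 in hypoxia and 0.62 in lactate and MT-RNR2 by 0.98 and 0.59, both chosen after their values were seen. Reads from mitochondrial DNA would raise all mitochondrially encoded genes. The 13 protein-coding ones had a median of -0.40 in hypoxia and -0.01 in lactate, and of 14 mitochondrial transfer RNAs 2 rose and 4 fell in hypoxia. A small share of such reads could still be hidden beneath abundant transcripts, so a part played by them stays open. More capture of RNA without a poly(A) tail predicts a rise of small noncoding RNAs and of replication-dependent histones, which mostly lack the tail too. Some histone transcripts measured here may carry a tail. In hypoxia 39 small noncoding RNAs had a median of 0.344 (bootstrap 95% interval 0.0963 to 0.624), but 20 histones one of -0.626 (-1.48 to -0.152). In lactate the small noncoding RNAs had -0.232 (-0.300 to -0.0346), but the histones 0.508 (0.179 to 0.733). These intervals come from drawing genes within the same libraries, so they leave out the variation between libraries. Of the 39 small noncoding RNAs, 5 passed upward and 1 downward in hypoxia, and 0 passed in either direction in lactate. Histone levels also follow DNA replication. Of 51 DNA replication genes, 8 rose and 22 fell in hypoxia, where the histones were lower. In lactate 0 rose and 2 fell, so the rise of histones there had no matching rise of those genes. In each treatment one class went with the explanation by capture and the other against it. Capture could thus be part of the rise of ribosomal RNA in either treatment, and of that of histones in lactate, and cannot be told apart from a biological change.

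Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split gave 7695 genes in hypoxia, 442 in lactate and 8205 between hypoxia and lactate, and the highest other split gave 0 genes by edgeR in each. Every other split mixes the 2 groups compared, so their difference widens the spread within groups and favours 0 calls. The 0 therefore does not argue against chance. For lists, the real splits gave 14, 19 and 14 and the highest others 11, 14 and 14. The real count was reached by 1 split in each test except for lists between hypoxia and lactate, where 2 reached it. For genes changed in both treatments, 2 of 100 drawn splits of the 9 libraries gave as many as the real 173. Only 2 of the 100 kept the 3 hypoxia libraries together, the real one included, and the others mix the large effect of hypoxia into several groups, so the count does not decide whether chance gives the overlap. The highest other split gave 6349, with all 3 hypoxia libraries in the place of the controls. The structure of the samples behind that count is the effect of hypoxia, which then enters both comparisons, so the count tests nothing further.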
